A study of Homo sapiens with 6 samples.

How the data were processed

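Total RNA of MCF-7 cells, 3 samples of the control siNC and 3 of siZ5, was made into Illumina libraries, per the labels. The deposited table holds 57820 rows, 9 of them repeated header lines, with columns for FPKM (fragments per kilobase of transcript, scaled to the library) and for raw counts per library. HISAT2, an aligner, and Cufflinks, which gives FPKM, are named without versions in the submitters' processing notes, which also name mm9, a mouse genome build that cannot lie behind human gene identifiers. The build, annotation, counter and strand setting used by the authors are not given in the sources used here. The count columns as deposited by the authors hold whole numbers that were not normalised.

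The table was usable in part. In its leading 9949 rows, 17.2% of all, gene identifier, FPKM and count belong together: of 2306 such rows with at least 50 counts in every library, 2297 had a ratio of count to FPKM, after scaling by the library total, that was constant over the libraries within an SD of 0.02 on the log2 scale. From there on the header line recurs 9 times, and identifiers, symbols and FPKM run on in steady steps, as when cells are filled down in a spreadsheet: 47844 of 47862 FPKM values lie on straight lines, and 0 of 2844 rows checked met the same tolerance. The counts of those rows vary as counts do but belong to no gene name, so they were kept out of the library sizes and tests of the named genes, except in 1 alternative fit on all rows; they hold the counts that the 17.3% to 17.4% in named rows leave. Loci outside the named rows were not analysed here. The FPKM of the named rows served for this check and for 1 alternative filter. Of the named rows, 7 symbols had turned into dates and were restored from the gene identifier through a name table. GENCODE version 29 (GRCh38), which is not the authors' annotation, served for chromosome, transcript length, GC content, 3′ UTR sequence, overlaps and gene order, and no start or end positions are printed. No per-sample column was left unused.

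Genes were filtered with filterByExpr and scaled with the trimmed mean of M-values over the named rows, and siZ5 was compared with siNC in edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest, group as the only term). Fold changes are siZ5 over siNC, and the standard error is the absolute log2 fold change divided by the square root of the F statistic. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Normalised counts are counts scaled to the common effective library size over the named rows, given as mean ± SD of 3 libraries. Before the data were examined, FPKM had been assumed and limma planned for them. The design also named edgeR for the case of counts, and that test was used. The filter in the design, a minimum mean FPKM below that of the alternative filter at 5 FPKM, was not run. FilterByExpr took its place.

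On counts simulated from these libraries with 200 changed genes, run on 3085 genes, the edgeR test recovered 39 of 98 genes changed by 0.5 on the log2 scale (39.8%) and 77 of 97 changed by 1 (79.4%), with 7 false among 123 calls (5.69%). In this simulation changes of 0.5 were therefore missed more often than found. Each simulated gene had the spread of the trend at its count level, so genes of tighter spread can pass at smaller changes. The 251 genes called in the real data had a median absolute log2 fold change of 0.40. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 26.5 and 30.7 for each pair, so no library was counted as a repeat of another.

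Gene lists were fixed before the data were examined. Of 35 lists, 18 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 between genes; 13 had 1 or 2 tested members and 4 had none. Calls adjusted over the list alone are given beside those over all genes. The genes named are, by a rule fixed in advance, the 10 with the largest rise and the 10 with the largest fall among called genes with a symbol, at least 50 normalised counts in the higher group and no overlap between the libraries of the groups; up to 4 members with the smallest p of each list described; and FAT1, RUNX1 and YBX1. Other genes named for carrying a UTR word or lying beside a changed gene were chosen after their values were seen.

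For the 3′ UTR, the longest annotated UTR of each gene was taken, and log2 fold changes, held within 2 of 0, were regressed on the presence of each 7-base word with UTR length and GC content as covariates, for words found in at least 20 genes and absent from at least 20. Words were ranked by t, the slope divided by its standard error. The lowest t was compared with 1000 permutations of the residuals. This was done over all words and over the 34 words that span or flank the joined ends of FAT1 exon 2 by up to 20 bases. Neighbouring genes were compared with 10000 permutations of the calls. The word test was tried on a planted shift and the neighbour test on permuted calls, and both treat genes as independent, which they are not. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

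Alternatives fixed in advance were no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization with limma 3.58.1, DESeq2 1.42.0, the replicate number as a block, other thresholds, summed symbols, an estimated correlation, fry in place of camera, and each library left out in turn. Corrections for GC content and length, a fit on all rows and the YAP/TAZ list without CYR61 were added after the data were seen.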

Results

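RNA sequencing compared cells labelled as MCF-7, an estrogen receptor-positive human breast cancer line. A group called siZ5, labelled as a knock-down of circFAT1(e2), was set against a control group called siNC. CircFAT1(e2) is a circular RNA made by joining the end of exon 2 of FAT1, a giant cadherin gene, back to the start of the same exon. Each group held 3 libraries of total RNA. The total counts over all rows of the deposited table were 60863661, 61682344 and 51543513 for siNC replicates 1, 2 and 3. They were 60166620, 52799942 and 55991013 for siZ5 replicates 1, 2 and 3. Only the rows that still carried a usable gene name were compared, and these held 17.3% to 17.4% of the counts of each library, between 8988293 and 10710240. Of the 9949 named rows, 4793, 3701 and 478 lay on chromosomes 1, 2 and 3, and 974 had no place in the annotation used, so the comparison covers a part of the genome and not the rest. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

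The series asks which genes lie downstream of circFAT1(e2). FAT1, the host gene, and RUNX1, a transcription factor named in earlier work on this circular RNA, were not analysed here. A count of FAT1 would measure mainly its linear mRNA and not the circle. The labels were thus not checked against the level of the target, which gene counts do not give. YBX1, a DNA- and RNA-binding protein also named in that work, was at 87449 ± 1006 normalised counts in siNC and 87363 ± 763 in siZ5 (SD, n = 3 each), and its log2 fold change was -0.00 ± 0.02 (SE) with an edgeR adjusted p of 0.975.

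Cells of the siZ5 group had higher levels of CYR61, a secreted matrix protein gene induced by the transcriptional co-activator YAP, and lower levels of LPGAT1, a lysophospholipid acyltransferase gene, and HJURP, the chaperone that loads the centromeric histone CENPA. CYR61 (ENSG00000142871.11, chromosome 1) rose from 9968 ± 299.9 normalised counts in siNC to 26373 ± 2818 in siZ5 (SD, n = 3 each), a log2 fold change of 1.40 ± 0.08 (SE) with an edgeR adjusted p of 0.000237. LPGAT1 (ENSG00000123684.8, chromosome 1) fell from 9139 ± 29.7 to 3609 ± 482 (log2 fold change -1.34 ± 0.09, edgeR adjusted p 0.00064). HJURP (ENSG00000123485.7, chromosome 2) fell from 4215 ± 102 to 1954 ± 88.7 (log2 fold change -1.11 ± 0.06, edgeR adjusted p 0.000237). ADAM15, a membrane-anchored metalloprotease gene with the lowest p-value of all genes tested, rose from 7518 ± 105 to 14196 ± 508 (log2 fold change 0.92 ± 0.04, edgeR adjusted p 0.000174). Among 3155 genes tested, 251 passed an adjusted p of 0.05, of which 139 rose and 112 fell. Most of these changes were small: the median absolute log2 fold change of the 251 genes was 0.40, or 1.32-fold, and 6 risen and 10 fallen genes changed by a factor of at least 2. In all 251 genes the 3 siZ5 libraries lay entirely above or below the 3 siNC libraries; over all genes tested this held for 943 genes, 29.9%, where chance gives 10%.

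Others of the 10 largest rises were CHRM3 (muscarinic acetylcholine receptor, log2 fold change 1.15), TYW3 (a tRNA-modifying enzyme, 1.10) and LYPD6 (1.06). NES (the intermediate filament nestin, 0.96), UBP1 (a transcription factor, 0.93) and DDAH1 (which breaks down methylated arginines, 0.91) also belong to them. TYW3 rose from 1225 ± 59.0 to 2621 ± 208 normalised counts. Others of the 10 largest falls were those of FAM73A (now MIGA1, a mitochondrial fusion factor, -1.30) and ATPAF1 (an assembly factor of the mitochondrial ATP synthase, -1.02). GJB3 (a gap junction connexin, -1.01) was also among them. FAM73A fell from 1400 ± 97.3 to 568 ± 63.3 normalised counts. RP11-504P24.6, annotated in the file as a long intergenic RNA, rose from 8.63 ± 3.25 to 116 ± 32.0 normalised counts. Its log2 fold change of 3.75 ± 0.39 (SE, edgeR adjusted p 0.00172) was the largest of the 10 rises, from a low count in siNC. It is not in GENCODE version 29, so its overlaps with other genes were not checked. RP11-504P24.4, now listed as a SEPTIN7 pseudogene, fell from 225 ± 29.9 to 79.4 ± 27.0, and sharing of its reads with the parent gene was not tested.

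The calls of 6 of the 20 largest changes were lost in at least 1 of the 6 fits that left out 1 library. Such fits have fewer samples and less power for every gene, so a lost call does not show that 1 library made it. NEB (nebulin, log2 fold change -1.56) was no longer past the threshold without any 1 of the 6 libraries, at edgeR adjusted p from 0.0570 to 0.125. ZNF860 (1.38) lost its call without siNC replicate 2 or any 1 of the siZ5 replicates, at adjusted p from 0.0878 to 0.104, and RQCD1 (now CNOT9, -0.96) without siNC replicate 3 or any 1 of the siZ5 replicates, at 0.0566 to 0.104. RP11-504P24.4 lost its call without siNC replicate 1, siZ5 replicate 2 or siZ5 replicate 3, at 0.0560 to 0.0578. EDN2 (endothelin 2, -1.23) and NR5A2 (an orphan nuclear receptor, -0.99) lost theirs without siNC replicate 1 or siZ5 replicate 3, at 0.0551 and 0.0579 for EDN2 and 0.0511 and 0.0512 for NR5A2. Whether strand was used in counting is not given in the sources used here, and overlaps matter for some genes. Of 39 named genes checked, 17 have exon bases that overlap another gene and 21 have none. Of the annotated exon bases of TYW3, 5.57% overlap the opposite-strand gene CRYZ, and of those of DDAH1, 8.38% overlap a long noncoding RNA on the same strand. For ADAM15, 4.65% overlap DCST1 on the same strand. Among called list members, HSPD1 (6.62%), RPL15 (6.27%) and STAT1 (5.57%) overlap genes on the opposite strand.

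**Figure D1:**
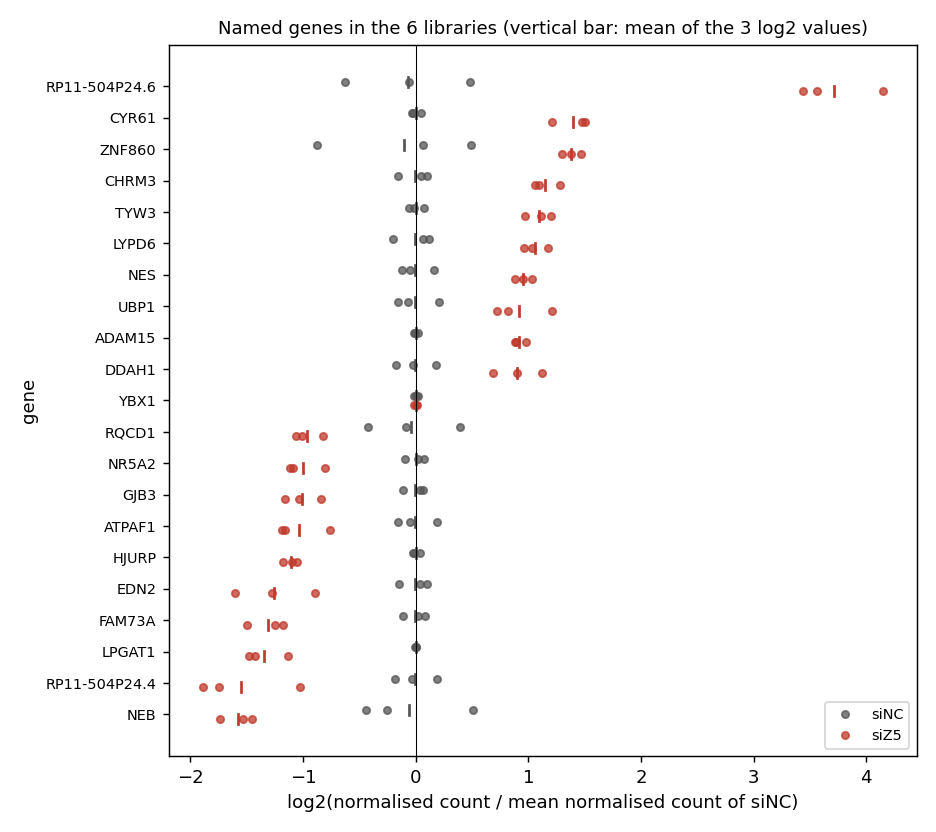
Normalised counts of the named genes in each of the 6 libraries, as log2 of the ratio to the mean of the siNC libraries (horizontal axis), with 1 row per gene, siNC in grey, siZ5 in red and the mean of the 3 log2 values as a vertical bar. The siZ5 libraries lie apart from the siNC libraries for the 10 risen and 10 fallen genes, as the rule that picked these genes requires. For YBX1, fixed by name, they lie on top of them.

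Targets of YAP and TAZ, the co-activators restrained by the Hippo pathway, were the only list past camera, a test against all other genes, at the preset correlation (adjusted p 0.000234), and did not pass with an estimated correlation (0.543). Without CYR61 the adjusted p of the list was 0.189, and with only the 5 members of at least 5 FPKM it was 0.447. Of 8 tested members, 3 rose, 0 fell and 5 did not pass, and 4 passed when adjusted over the list alone. Beside CYR61, F3 (tissue factor) rose from 441 ± 5.22 to 679 ± 25.9 normalised counts (log2 fold change 0.62) and TGFB2 (transforming growth factor beta 2) from 841 ± 77.6 to 1292 ± 110.0 (0.62), though 26.6% of the annotated exon bases of TGFB2 overlap a noncoding RNA. NUAK2, a kinase gene, had a log2 fold change of 0.38 with an edgeR adjusted p of 0.0508, and GADD45A had -0.24 with no call. MOB1A, an activator of the Hippo kinases LATS1 and LATS2, fell from 9644 ± 684 to 7107 ± 254 normalised counts (log2 fold change -0.44, edgeR adjusted p 0.00571). VGLL4, a competitor of YAP, did not pass (0.20, adjusted p 0.179). These were the 2 tested members of the list of FAT cadherins and Hippo kinases, and both passed when adjusted over the list alone.

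Metabolic and mitochondrial lists held a few clear rises among members that did not pass. Of 6 tested nuclear-encoded respiratory chain genes, 2 rose: NDUFS2, a complex I subunit, from 4680 ± 36.9 to 6882 ± 219 normalised counts (log2 fold change 0.56), and SDHB, a complex II subunit (0.32); 2 passed when adjusted over the list alone. Of 5 tested genes of cholesterol synthesis and SREBP2 targets, 2 rose, DHCR24 (0.45) and PMVK (0.42), and FDPS was at -0.18 without a call; 3 passed when adjusted over the list alone. PMVK lost its call without siNC replicate 1 or siNC replicate 2, at edgeR adjusted p of 0.0560 and 0.0565. Of 12 tested MYC targets and ribosome biogenesis genes, 2 rose, the mitochondrial chaperone HSPD1 (0.31) and ornithine decarboxylase ODC1 (0.20), and 3 passed when adjusted over the list alone; CAD was at 0.19 with an adjusted p of 0.0598. Of 4 tested genes of the ATF4 stress response, PHGDH, the entry enzyme of serine synthesis, rose (0.34), MTHFD2 was at 0.28 with an adjusted p of 0.0703, and 2 passed when adjusted over the list alone. None of these lists passed camera, at adjusted p of 0.089 for the respiratory chain (0.0159 with no filter, 0.410 with a filter at 5 FPKM and 0.560 with an estimated correlation), 0.269 for cholesterol synthesis, 0.251 for MYC targets and 0.269 for the ATF4 response.

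Cell cycle, p53 and interferon lists held few calls. CENPF, a kinetochore gene, rose (log2 fold change 0.30) as 1 of 6 tested mitotic genes, of which 1 passed when adjusted over the list alone. RRM2 was past the threshold (0.15) as 1 of 3 tested genes of DNA replication, with 1 adjusted over the list alone. It was not without any 1 of the 6 libraries, at edgeR adjusted p from 0.062 to 0.115, and 20.2% of its annotated exon bases overlap another gene. Of 6 tested p53 targets 0 passed with edgeR over all genes, 4 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone: XPC (0.34), PLK3 (-0.37) and BTG2 (-0.42). DESeq2 called XPC and PLK3. Of 5 tested genes of the response to interferon and double-stranded RNA, STAT1 was past the threshold at -0.26, with 2 adjusted over the list alone; STAT1 lost its call without siNC replicate 2 or 3 or any 1 of the siZ5 replicates, at adjusted p from 0.0586 to 0.127. ISG15 (0.10) and IFI6 (0.03) did not pass. Of 5 tested genes of the small RNA machinery, AGO3 fell from 2107 ± 109 to 1513 ± 137 normalised counts (-0.48), with 1 adjusted over the list alone; it lost its call without siNC replicate 1 or siNC replicate 3, at adjusted p of 0.0692 and 0.0702. Among 6 tested ribosomal protein genes RPL15 was past the threshold (-0.15), with 1 adjusted over the list alone, but not without siNC replicate 1, 2 or 3 or siZ5 replicate 2 or 3, at adjusted p from 0.11 to 0.144. None of these 6 lists passed camera, the lowest adjusted p being 0.626.

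No call was made by edgeR among 6 tested hypoxia targets, 3 glycolysis, 4 mesenchymal, 4 immediate early and 3 TGF-beta target genes, 6 apoptosis regulators and 5 splicing factors. At an unadjusted p under 0.05 these numbered 3 hypoxia targets, 2 immediate early genes, 3 apoptosis regulators, 3 splicing factors and 0 in the other lists. Of the 4 members with the smallest p of each list, DESeq2 called PDK1 and no other. Adjusted over the list alone, 3 hypoxia targets (PDK1 at -0.38, EGLN1 at 0.14 and INSIG2 at -0.23) and 1 splicing factor (HNRNPU at 0.11) passed. Of the markers of other cell types, S100A2, a basal epithelial marker, was at 0.24 and COL3A1, a fibroblast marker, at 0.36, both without a call, and no endothelial or leukocyte marker was tested, since 1 of 10 and 2 of 14 of them, respectively, were among the named rows and these did not pass the filter.

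**Figure D2:**
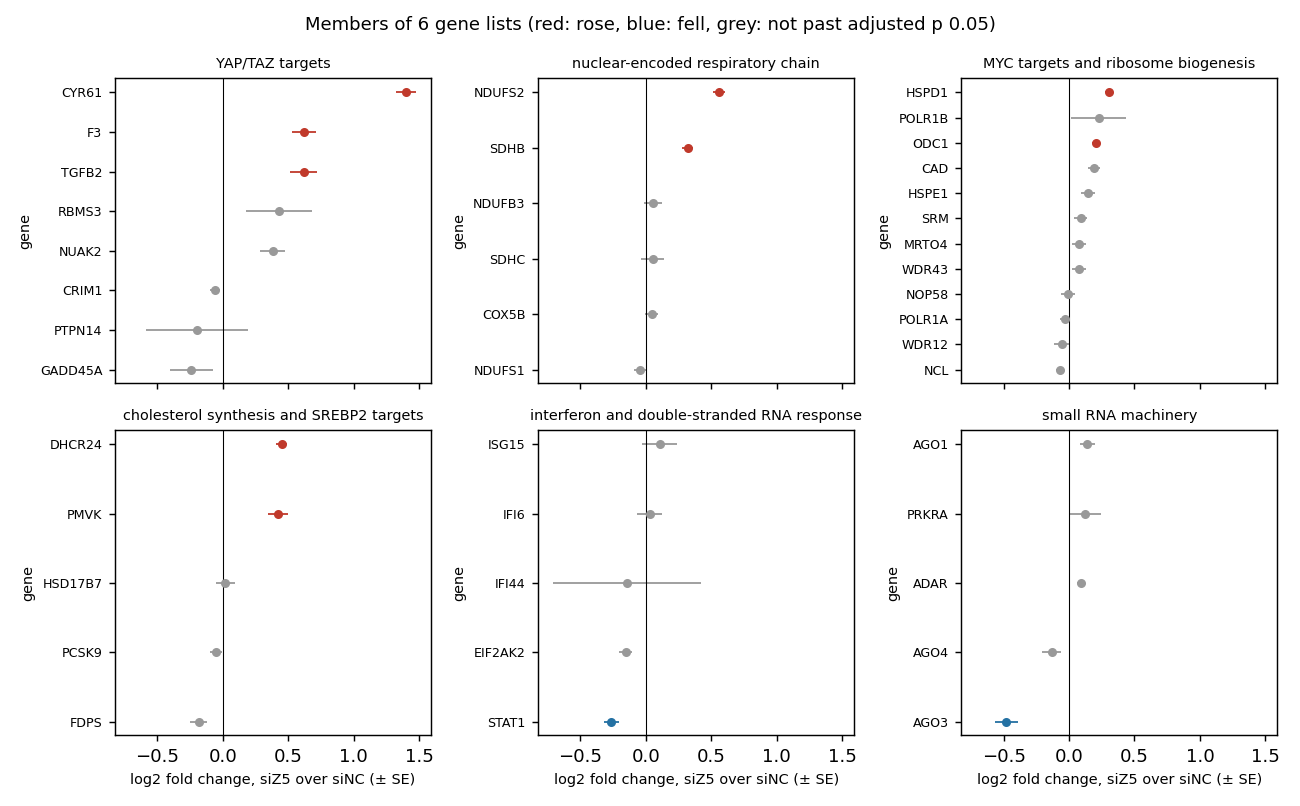
Log2 fold changes of siZ5 over siNC (horizontal axis, with standard errors as bars) of every tested member of 6 gene lists, 1 panel per list and 1 row per gene, in red where a gene rose, in blue where it fell and in grey where it did not pass an adjusted p of 0.05. CYR61, at 1.40, lies farthest from 0, and 3 of 8 YAP/TAZ targets rose.

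Fallen genes carried a short sequence in the 3′ untranslated region (UTR) more often than risen genes. The word GACAGTT stood in the annotated 3′ UTR of 42 of 103 fallen genes (40.8%), 12 of 132 risen genes (9.09%) and 265 of 2078 genes that were not called (12.8%). The word was picked for the lowest t of all words on these same fold changes, so these shares are no separate test. The UTRs of fallen genes were also longer, with medians of 2619 bases against 1714 for risen genes. LPGAT1, FAM73A, ATPAF1 and GJB3 carried it, as did JAK1 (log2 fold change -0.48), AGO3 and STAT1 among the genes that fell, and CYR61 and ODC1 among those that rose. Over all 2313 genes with a 3′ UTR of at least 50 bases, genes with the word were on average lower in siZ5 by 0.16 ± 0.02 (SE) on the log2 scale, adjusted for UTR length and GC content (slope -0.16, 319 genes with the word). This was the lowest t of 15954 words of 7 bases, at -6.87, followed by -3.93 for the next, and its permutation p over all words was 0.001, the smallest that 1000 permutations give. The word is also found in exon 2 of FAT1, 1 time, at bases 7 to 13 of the exon, next to the junction at which the circular RNA is closed.

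**Figure D3:**
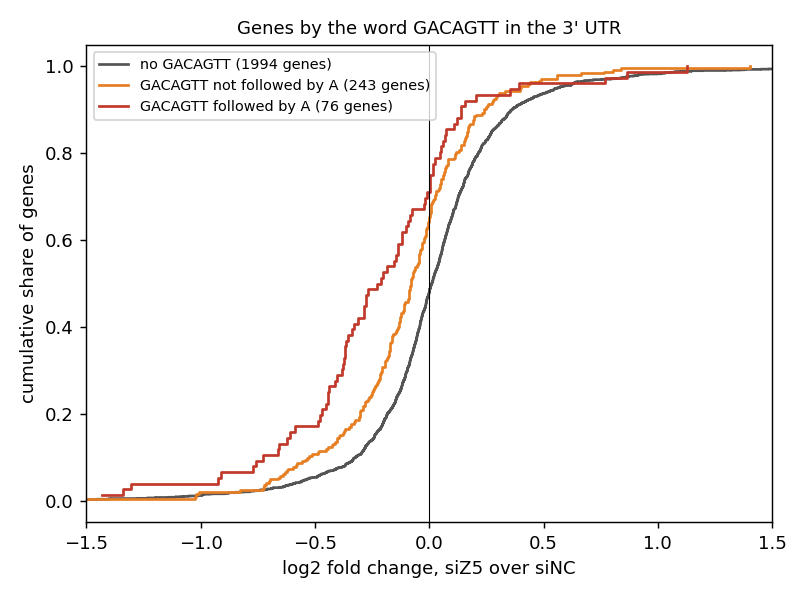
Cumulative share of genes (vertical axis) by log2 fold change of siZ5 over siNC (horizontal axis, limited to ±1.5, with 18 genes outside), for 1994 genes without GACAGTT in the 3′ UTR, 243 genes with it not followed by A and 76 genes with it followed by A. The curves of genes with the word lie to the left, with medians of 0.01, -0.08 and -0.22 in that order.

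The changes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment on 3 against 3 libraries. The count of 251 changed genes was 145, 162, 139 and 147 without siNC replicate 1, 2 or 3 or siZ5 replicate 3, respectively, and the count of 112 fallen genes was 74 without siZ5 replicate 2.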

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

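The test of the rows without a gene name was chosen after the table had been seen. Counts outside the named rows, which no comparison above uses, also differed between the groups: in a fit on all rows, 14411 rows without a usable gene name were tested and 1092 changed in siZ5, 665 upward and 427 downward, with 3245 at an unadjusted p under 0.05. That is 7.58% of these rows, against 7.61% of the named rows in the same fit, and 62 rose and 22 fell by a factor of at least 2. Which genes these rows stand for was not analysed here, and no explanation was tested.

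The count of changed genes was also taken for every division of the 6 libraries into 3 against 3, of which there are 10. The real division gave 251 genes and the highest of the others gave 1, so that 1 of the 10 reached the real count. With 10 divisions the share can never be under 0.1. Every other division mixes siNC and siZ5 libraries on each side, so a difference between the groups adds to the spread within the sides. The low counts of the other divisions therefore do not measure what chance alone would give.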

How the results depend on the processing

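The GC and length corrections, the fit on all rows and the list without CYR61 were chosen after the data were seen. The count of 251 changed genes (139 up, 112 down) stayed within 1.5 times under no filter, a filter at 5 FPKM, both other scalings, DESeq2, summed symbols, both corrections and all rows, ranging from 208 to 350. It was 16 (6 up, 10 down) with an absolute log2 fold change of at least 1 and 430 (226 up, 204 down) at an adjusted p under 0.1, both by construction. Leaving out 1 library gave 139 to 216 genes, 85 to 118 up and 54 to 98 down, with fewer samples in each fit. With the replicate number as a block 140 genes passed (76 up, 64 down), 136 of them shared; same-numbered libraries did not deviate together (correlations 0.0081, 0.0021 and 0.0010, none the best for its library), so the numbers were not taken as pairs. Of 18 lists, 1 passed camera; of 19 lists with enough members 2 passed with no filter, the added list being the nuclear-encoded respiratory chain (adjusted p 0.0159), of 14 lists 0 with a filter at 5 FPKM, which leaves fewer members, and of the 18 lists 0 with an estimated correlation, 5 with fry for 1 direction and 13 with fry for either direction, which do not compare a list with other genes. The YAP/TAZ list was at adjusted p of 2.82e-07 to 0.00944 under its other alternatives, except 0.447 at 5 FPKM, 0.543 with an estimated correlation and 0.189 without CYR61. Over 104 named genes and their alternatives, 1540 of 1630 values kept their side of the threshold, 67 lost a call, 23 gained 1 and 0 reversed. Pseudocounts of 0.1 and 0.5 were not run, since the values are counts, and FAT1 was not analysed here. Depth and spread limit what is seen: genes changed by 0.5 on the log2 scale were recovered in 39.8% of simulated cases, whose spread followed the trend over counts.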

Other observations

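The tests of the divisions of the libraries for the UTR word, of microRNA hairpins, of miR-548g-3p beside the word and of GC content without the word, and the corrections for GC content and length with the GC differences after them, were chosen after the data were seen. Several lists with 1 or 2 tested members held a changed gene. HIST2H2BE (now H2BC21), a histone gene that also makes polyadenylated RNA, fell from 1478 ± 73.0 to 954 ± 130 normalised counts (log2 fold change -0.63, edgeR adjusted p 0.0154), but not past the threshold without siNC replicate 2 or siNC replicate 3 (adjusted p 0.0624 and 0.0601), and its reads may be shared with other histone genes, which was not tested. PDIA6, a protein disulfide isomerase of the endoplasmic reticulum, fell (-0.34, adjusted p 0.00503), with 25.2% of its annotated exon bases overlapping an opposite-strand gene. GCLM, the regulatory subunit of the enzyme that starts glutathione synthesis, rose (0.33, adjusted p 0.0164) and lost its call without siNC replicate 2 or 3 or siZ5 replicate 2 or 3 (adjusted p from 0.0568 to 0.0676). The estrogen response genes PDZK1 (0.11) and GREB1 (-0.07) did not pass. Neither did the luminal genes ERBB4 (0.84, edgeR adjusted p over 0.05) and MUC1 (0.04), nor EPCAM (0.08). Mean normalised counts in siNC were 127 for PDZK1, 301 for GREB1, 36.2 for ERBB4, 1372 for MUC1 and 110 for EPCAM. Of 4 tested mesenchymal genes, TWIST2 was at 1350, FN1 at 589, ZEB2 at 554 and COL3A1 at 30.7 normalised counts in siNC. The name of the line is taken from the labels. Whether the luminal and mesenchymal levels are usual for this line was not tested.

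Genes with GACAGTT in the 3′ UTR had lower log2 fold changes on average than genes without it (slope -0.16 ± 0.02), though of 319 such genes 42 fell, 12 rose and 265 did not pass. A candidate explanation is binding of the siZ5 oligonucleotide to other transcripts. The word lies at the circle's junction, where a guide pairing from its seed (positions 2 to 8) would cross the joined ends. A shared word was predicted. The same word had the lowest t of all words and of the 34 junction words. In both tests its permutation p was 0.001, the smallest possible. Release of miR-548g-3p, a microRNA named in earlier work on this circle, was tested by its seed match, which had a slope of -0.0144. The 95% interval from -0.0552 misses the bound of -0.05 set beforehand, so that test leaves it open. The seed match shares 6 bases with the word. A later fit beside the word gave 0.0153 (95% interval -0.03 to 0.06). This interval lies above -0.05 and argues against a fall of that size, though the fit was chosen after the data were seen. A smaller effect stays open. Release of another microRNA with the same seed stays open. The complement of the word stands in 3 of 1881 annotated microRNA hairpins. It was sought anywhere in the hairpin and not at the seed, so this count cannot decide the question. The 10 divisions of the libraries are too few for a share under 0.05: 1, the real one, had a t of -6.28, and the lowest other -3.28. Every other division splits the siZ5 libraries unevenly and keeps a part of the difference, with its sign taken as negative. The -3.28 is therefore no chance level. Against the siNC mean, siZ5 replicates 1, 2 and 3 had slopes of -0.161, -0.167 and -0.171. Against the other siNC libraries, siNC replicates 1, 2 and 3 had -0.002, 0.010 and -0.023. The word was picked on these same libraries. With 1 oligonucleotide, whose sequence is not given in the sources used here, effects of losing the circle and of seed pairing may both be in the 251 genes; 61 of 103 fallen genes with a UTR lack the word, and a second oligonucleotide would separate these.

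Risen and fallen genes differed in GC content, with medians of 48.5% and 43.4% against 47.7% for all genes and a mean difference of 4.15 points (permutation p 2e-04). Over the 3016 genes with a GC value, the Spearman correlation of log2 fold change with GC content was 0.0415. The level of high-GC against low-GC genes was -0.0612, 0.0582 and -0.0160 in siNC replicates 1, 2 and 3. It was -0.0132, 0.0099 and 0.0224 in the siZ5 replicates, within the siNC range. After a correction for transcript GC content within each library the mean difference was 1.56 points (permutation p 0.1, 37.6% of its size). Counting that depends on GC content therefore stays open as the source of the difference, though these library values show no clear shift between the groups. A difference in biology that follows GC content, which the correction would also remove, stays open too and was not tested. The bound set beforehand, that at least 80% of the changed genes stay past the threshold, was met at 93.2% but was wrong for this question, since it measures the calls and not their GC difference. After a correction for transcript length 97.6% stayed and the mean difference was 3.72 points (permutation p 3e-04), which argues against length as the whole source. Without the genes with GACAGTT it was 3.31 points (permutation p 0.006), 79.8% of its size, so they are not the whole source; a bound asking that at least 80% remain was missed and replaced by the permutation p after this value had been seen, and a part played by the word stays open.

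Genes next to each other among those tested changed together more often than in permutations of the calls. The permutations ran over all tested genes and did not hold the GC content or count level of neighbours. Pairs in which both genes changed lay up to 1705181 bases apart, and a gene can stand in more than 1 pair. Of 3013 pairs of neighbouring tested genes, 18 had changed in the same direction, against 10.1 in the mean of permutations (permutation p 0.0118), and 7 in opposite directions, against 10.0. Reads of overlapping transcripts counted for both genes would put such pairs close together, but of 1691 pairs at least 5 kb apart 14 had changed in the same direction, against 5.70 (permutation p 0.0012), and of 728 overlapping pairs 1 had. Examples are JAK1 and AK4, which both fell and both carry GACAGTT, SERTAD4 and HHAT, which rose, and ATAD3A and ATAD3B, near-identical copies whose reads may be shared. CYR61 and DDAH1, both among the 10 largest rises, are neighbours on opposite strands at a shorter distance; control over a shared stretch of chromosome stays open and was not tested.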
